A study of Danio rerio with 9 samples.

How the data were processed

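Gene expression was measured in zebrafish (Danio rerio) embryos at 9 stages of early development: 64-cell, high, sphere, 30% epiboly, 50% epiboly, shield, 75% epiboly, 90% epiboly and tailbud. Per the labels' protocols, between 30 and 50 uninjected embryos of outbred wild-type stock, kept at 28.5 °C, were pooled per stage from a single clutch. From 800 ng of total RNA an antisense RNA was amplified and coupled to a dye. Each stage was hybridised once, on 1 spotted oligonucleotide array with 2 colours. On all 9 arrays the labels give the stage RNA as Cy5 (red) and a common reference, a pool of equal amounts of total RNA of the 9 stages, as Cy3 (green). The series text speaks of dye-swapped hybridisations. No array with the dyes exchanged was analysed here, so a dye effect of a probe stays in its ratio to the pool, while one that is constant over arrays cancels between stages.

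The deposited scanner tables hold, per spot and channel, the mean and median spot intensity and the local background on a linear scale, per the file headers; these values were not normalized. The image software's settings and its flag codes are not given in the sources used here. The deposited value table of the series holds log2 values by the authors. Set against the scanner tables, they equalled log2 of red over green, each as spot mean minus background mean and averaged over spots of an ID, within 0.001 for 99.2% of the IDs on the 64-cell array. The table was therefore read as stage over pool, on the log2 scale, neither centred nor normalized. Its column medians, in stage order, were 0.02, -0.90, -0.95, -0.80, -0.95, -0.89, -0.36, -0.41 and -0.51. The table writes the probe prefix with 1 letter changed, and its rows were matched with that letter replaced.

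From the scanner tables, spot means and background medians were corrected with normexp (offset 50) over all spots and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Log2 ratios of stage over pool were averaged over the spots of an ID. Of 16896 spots per array, 16340 carried a probe and 556 were controls or blanks, and the probe spots held 16178 IDs. A probe was tested when its spot median exceeded the local background median by 2 background SD in at least 1 channel on at least 3 of the 9 arrays, which kept 16107. This rule was lenient, because blank spots were themselves brighter than the local background. Signals are therefore also set against the 95th percentile of the 262 blank spots of the same array and channel.

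The stage trend was the slope of the log2 ratio on stage order (limma, 7 residual degrees of freedom). The fitted change is that slope over the whole series. Curvature was the quadratic term of an orthogonal polynomial (6 residual degrees of freedom). Both tests were two-sided with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. No stage had a replicate. The error of these tests is the scatter of 9 arrays around a curve, which mixes array noise with real departures, and stages of a single clutch are not independent samples. Between 2 stages no test was possible. The number of probes differing at least 2-fold is given as a description of those arrays.

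The groups, the tests, the rule for named genes and a first set of alternatives were chosen before the data were examined. That rule asked for the rising and falling genes with the largest fitted change, genes of either sign of curvature, members of fixed gene lists, textbook stage markers and the largest differences per step, all by gene symbol. The files do not pair the oligonucleotide IDs with gene names. Neither that rule nor the gene list test with camera could be applied, and no fixed list gave a result. The 2 rising and 2 falling IDs with the largest fitted change are given in their place. Only 2 IDs were accessions, of which 1 matched a gene, rarga, in the table of RefSeq names (assembly GRCz12tu, used for the name alone). The rarga probe was chosen because it could be named.

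Both tests were tested on simulated data with the real residual spread of the 16107 probes. The noise was drawn independently per probe and array, so errors shared by the probes of an array were not covered. For the stage trend, of 50 probes simulated with a change of 1 on the log2 scale 22 were called, of 50 with a change of 2 there were 34, of 50 with a change of 4 there were 45, and of 50 with a change of 0.5 there was 1. Among the unchanged probes 5 were called. For curvature, 196 of 200 simulated probes were called, with 12 calls among the others. All 200 had a quadratic term of the same size, of either sign, several times the 1.83 of the rarga probe given below. Smaller terms were not simulated. Precision is limited by the number of arrays. Alternatives covered background correction, normalization, filters on dim probes, textbook hours in place of stage order, the authors' value table, a rank correlation, a stricter size rule and leaving out each array. A block for slide or scan day was not fitted, as the files used here name neither.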

Results

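Transcript levels were followed through early zebrafish development, from cleavage (64-cell) through the blastula (high, sphere and 30% epiboly) and gastrulation (50% epiboly, shield, 75% epiboly and 90% epiboly) to the tailbud stage. Epiboly is the spreading of the blastoderm over the yolk. Each of the 9 stages was represented by 1 array on which stage RNA (Cy5) was set against a pool of all stages (Cy3), and no stage had a replicate. The median Cy5 signal of the probe spots ranged from 324.5 at the shield stage to 995 at the 64-cell stage, and the median Cy3 signal from 548 at shield to 1188 at 75% epiboly. The number of probe IDs with a stage signal above the 95th percentile of blank spots lay between 6531 at shield and 11274 at tailbud. Of the tested probes, 5804 exceeded that level at all 9 stages and 3441 at none.

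The first question was which transcripts had a linear trend with stage order from the 64-cell to the tailbud stage, whether or not they changed steadily. Of 16107 tested probes, 3789 rose and 3409 fell with stage order, together 44.7% of those tested. Loess centres each array on its own probes, so rise and fall are relative to those probes and are not amounts per embryo. The fitted change over the series was at least 2-fold for 2551 of the rising and 2380 of the falling probes. The median fitted change on the log2 scale was 1.35 among rising and -1.34 among falling probes. Among the 2551 rising probes the median ratio, relative to each probe's mean, went from -0.93 at the 64-cell stage to 0.72 at tailbud, and 49.4% of that difference lay between sphere and 30% epiboly. Among the 2380 falling probes it went from 0.83 to -0.66, with 52.9% of the difference at the same step. On the 6 arrays from 30% epiboly to tailbud alone, a period chosen after the data were seen, 1574 probes rose and 1782 fell. Of these 3356 probes, 2306 were called with the same sign over all 9 arrays. A rank correlation gave 2658 rising and 2182 falling probes, and the authors' uncentred value table gave 2103 and 2236. Whether rising or falling probes were more frequent depended on the scaling, as median centring gave 3595 rising and 3887 falling probes and the value table with medians subtracted, an alternative added after the data were seen, gave 3430 and 3767.

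The files do not pair these oligonucleotides with gene names, so the probes with the largest fitted changes are given by ID. CGENXEB_456011657_0 rose by a fitted 8.61 ± 0.60 (SE, 9 arrays) on the log2 scale (limma, adjusted p = 3.6e-05). Its ratio was -6.56 at 64-cell, -5.84 at sphere, -3.54 at 30% epiboly and 1.26 at tailbud. At tailbud its spot was near the top of the scanner's range. Tailbud exceeded 64-cell by 208-fold in the Cy5 channel after loess and Aquantile normalization. This is not a strict lower bound, because the 64-cell signal did not exceed the 95th percentile of blank spots. It is also open to dye bias that differs between arrays, since no balanced swaps were used. CGENXEB_456014230_0 rose by a fitted 8.12 ± 1.1 (adjusted p = 4e-04), with a ratio of -5.17 at sphere and -1.01 at 30% epiboly. For both rising probes the Cy5 signal of the first 3 stages did not exceed the 95th percentile of blank spots, so the low ratios there are poorly measured. The scanner software flagged the spot of CGENXEB_456014230_0 on 5 of the 9 arrays. CGENXEB_456011480_0 fell by 8.22 ± 1.3 (adjusted p = 0.00095), from a ratio of 0.94 at sphere to -3.66 at 30% epiboly. Its spot was near the top of the scanner's range at 64-cell, which exceeded tailbud by 118-fold in the Cy5 channel, with the same limit of dye bias. At 50% epiboly, shield and 90% epiboly its Cy5 signal did not exceed the 95th percentile of blank spots, and its spot was flagged on 3 of the 9 arrays. CGENXEB_456007473_0 fell by 7.71 ± 1.1 (adjusted p = 0.00045), from 1.77 at sphere to -2.11 at 30% epiboly, and remained above the blank spots at all 9 stages.

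The second comparison asked which transcripts followed a curved course over the series. The quadratic term passed the threshold for 1080 probes with a negative and 550 with a positive sign. The highest value lay between the end stages for 1059 of the 1080, and the lowest for 516 of the 550. A linear trend was also called for 492 and 257 of them, which left 588 and 293 with curvature only. The 588 probes had their highest median at 30% epiboly, 0.48 above each probe's mean, against -0.50 at 64-cell and -0.44 at tailbud. The 293 probes had their lowest median at 30% epiboly, -0.51, against 0.61 at 64-cell and 0.32 at tailbud. The counts of negative and positive terms depended on single arrays: without tailbud they were 75 and 19, without shield 361 and 138, without 50% epiboly 381 and 140, without 30% epiboly 462 and 192, without 90% epiboly 690 and 344, and without sphere 1881 and 1146. Which sign was more frequent depended on the scaling, as median centring gave 727 negative and 1009 positive terms, and the authors' uncentred value table gave 211 and 2851. Textbook hours in place of stage order gave 554 and 225.

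The probe for rarga (NM_131339), which encodes retinoic acid receptor gamma a, a nuclear receptor activated by retinoic acid, was lowest at 30% epiboly. Its log2 ratio was 0.44 at 64-cell, 0.30 at high, -0.36 at sphere, -1.29 at 30% epiboly, -0.86 at 50% epiboly, -0.92 at shield, -0.76 at 75% epiboly, 0.12 at 90% epiboly and 0.61 at tailbud. The quadratic term was 1.83 ± 0.25 (SE, 9 arrays; limma, adjusted p = 0.0076). Its level was 3.32-fold lower at 30% epiboly than at 64-cell and 3.74-fold lower than at tailbud, differences between single arrays without a test of their own. The linear term did not pass the threshold (fitted change -0.04 ± 0.65, adjusted p = 0.97), and its sign varied between settings. On the 6 arrays from 30% epiboly to tailbud alone, chosen after the data were seen, the probe rose by a fitted 1.80 (adjusted p = 0.0018; range over all alternatives 0.0018 to 1). Without the tailbud array the quadratic term was 1.40 and its adjusted p 0.056, past the threshold no longer. Over all alternatives the adjusted p of the quadratic term ranged from 0.00014 to 0.056. At shield its Cy5 signal did not exceed the 95th percentile of blank spots.

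**Figure D1:**
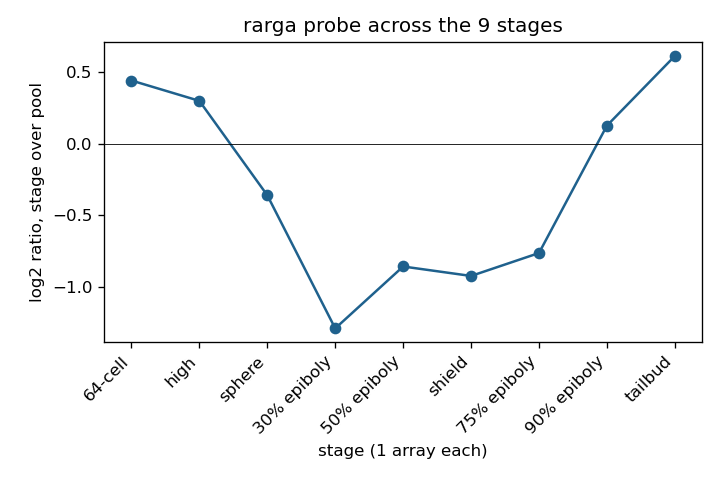
Log2 ratio of stage RNA over the pool (vertical axis) for the rarga probe at each of the 9 stages in order (horizontal axis), 1 array per stage and no error bars because there are no replicates. The ratio is 0.44 at 64-cell, lowest at 30% epiboly (-1.29) and 0.61 at tailbud.

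**Figure D2:**
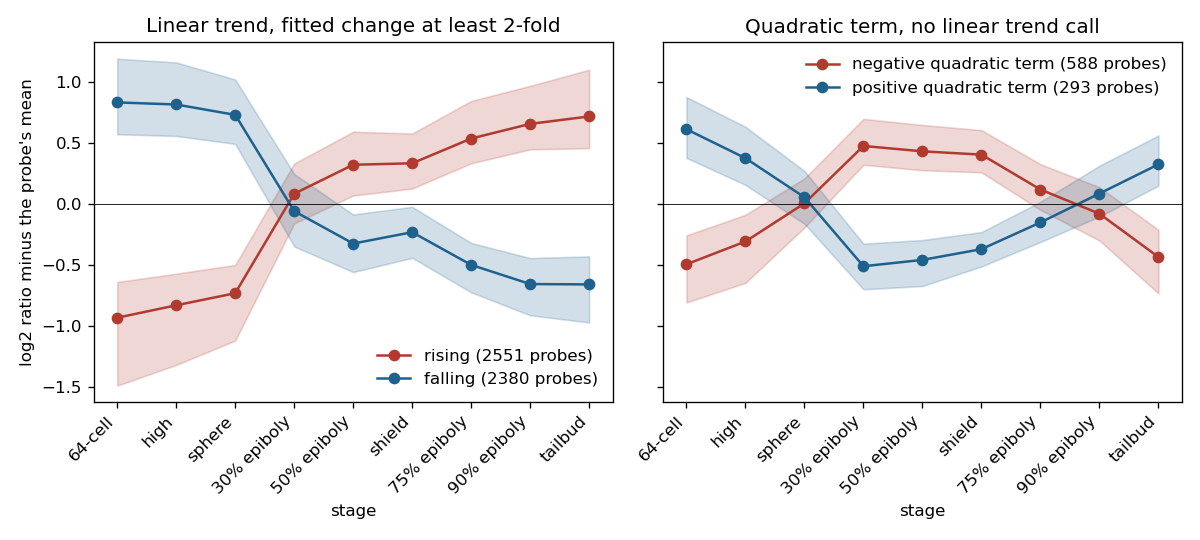
Median log2 ratio minus each probe's mean (vertical axis, points and lines) with the interquartile range over probes (shading) at the 9 stages, for probes with a linear trend and a fitted change of at least 2-fold (left) and probes with a quadratic term only (right). The medians of the 2551 rising and 2380 falling probes cross 0 near 30% epiboly, where the medians of the 588 probes with a negative and the 293 with a positive quadratic term are at their extremes.

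Consecutive stages were then set side by side to describe where in the series the profiles changed. Between sphere and 30% epiboly 2250 probes (14.0% of those tested) differed at least 2-fold, 1199 higher and 1051 lower at 30% epiboly. At the other 7 steps the number lay between 53 (50% epiboly to shield) and 366 (shield to 75% epiboly). From 64-cell to high there were 127 such probes, and from high to sphere 337. In the pool channel alone, where the same RNA was hybridised on every array, 66 probes differed at least 2-fold between the sphere and 30% epiboly arrays. That channel was quantile normalized between arrays, unlike the ratios. The stage channel processed in the same way gave 2541 probes at this step, 1148 from shield to 75% epiboly and 1012 from 75% to 90% epiboly. The 172 spots of the control CGENZFCTRL_40001_0, left out of these counts, had a mean log2 ratio of -0.84 at sphere and -0.21 at 30% epiboly. Between 64-cell and tailbud 2525 probes were higher and 2205 lower at tailbud. Which direction was more frequent depended on the scaling: median centring gave 2404 higher and 3042 lower probes for that pair, and 1102 and 1420 from sphere to 30% epiboly, and the value table with medians subtracted gave 2703 and 3507 from 64-cell to tailbud. With the authors' value table the step from sphere to 30% epiboly held 1572 higher and 1546 lower probes as deposited, and 1256 and 1876 with each array's median subtracted, an alternative added after the data were seen. As deposited, that table is not centred, and its step from 64-cell to high then held 16 higher and 5737 lower probes, against 61 and 66 after loess. In that uncentred table the step from 64-cell to high thus exceeded the step from sphere to 30% epiboly. Under the other settings with the 2-fold rule the step from sphere to 30% epiboly held between 1712 and 3132 probes. These are differences between single arrays, with no test.

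**Figure D3:**
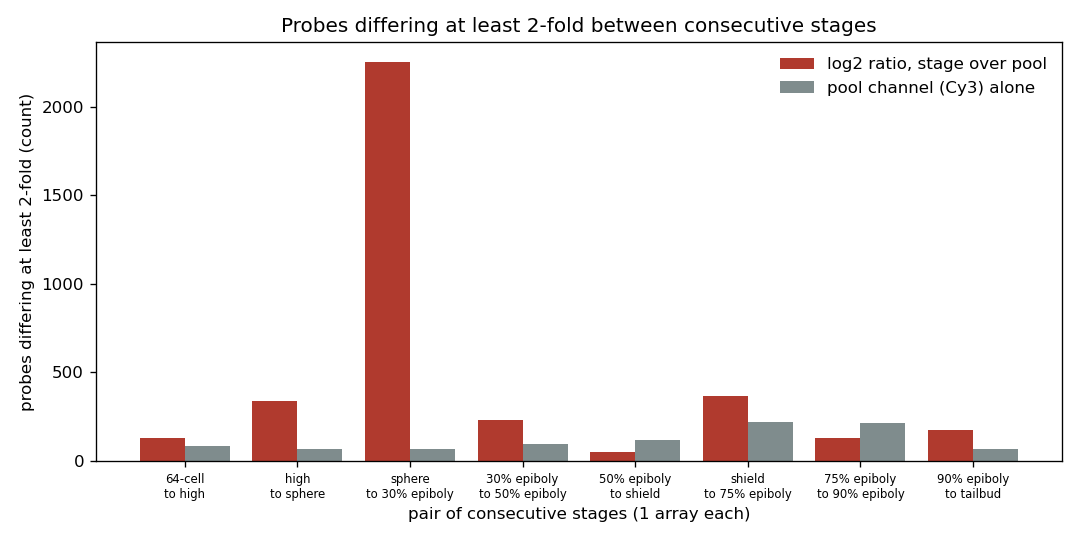
Number of tested probes differing at least 2-fold (vertical axis) between consecutive stages (horizontal axis), 1 array per stage. Red bars are the log2 ratio of stage over pool after loess, and grey bars the pool channel alone, quantile normalized between arrays. The red bar is 2250 between sphere and 30% epiboly and at most 366 elsewhere, and the grey bar at that step is 66.

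Across probes, which are not independent replicates, the log2 ratios of the 3 earliest stages resembled each other, with r = 0.94 between 64-cell and high and 0.87 between high and sphere. Between sphere and 30% epiboly r was 0.24. From 30% epiboly onward consecutive stages correlated at 0.63 (shield and 75% epiboly) to 0.82 (90% epiboly and tailbud). The 30% epiboly array correlated at 0.70 with 50% epiboly, 0.75 with shield and 0.36 with 75% epiboly. With 90% epiboly (0.23) and tailbud (0.05) its r was no higher than with sphere. Of the 36 pairs of stages 15 had a negative r, and the lowest was -0.45, between sphere and tailbud. In the authors' uncentred values 9 pairs had a negative r, the lowest was -0.16, sphere and 30% epiboly correlated at 0.42, and some signs differed, as for 64-cell and shield (0.12 against -0.20 after loess). All arrays had the same dyes per the labels and a pool of the same stages as reference, against which early and late stages can lie on opposite sides, so the direction was kept. The stage channel alone, quantile normalized, correlated positively for all pairs, with a lowest r of 0.74, and the pool channel at 0.96 to 0.99. In the stage channel r was 0.894 between sphere and 30% epiboly and 0.896 between 30% epiboly and tailbud.

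**Figure D4:**
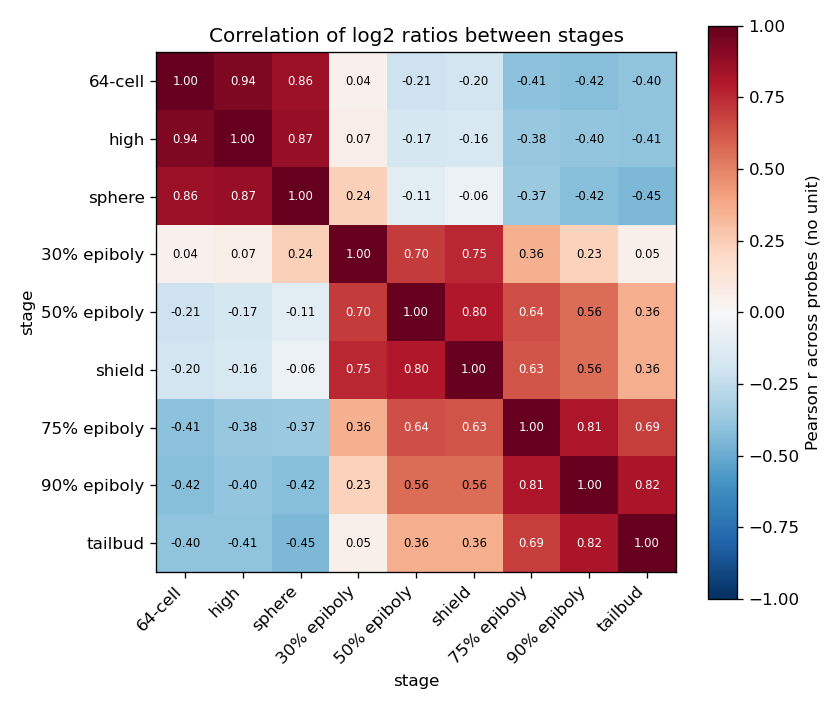
Pearson correlation across the tested probes of log2 ratios (colour and printed value, no unit) for each pair of the 9 stages, listed in order on both axes, 1 array per stage. The 64-cell, high and sphere arrays correlate at 0.86 to 0.94, and sphere with 30% epiboly at 0.24.

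Among the 2530 probes whose log2 ratio spanned at least 4-fold over the series, extremes were most frequent at its ends. The highest value fell at tailbud for 559 probes, at 64-cell for 423 and at high for 386, and at shield for 106. The lowest value fell at 64-cell for 917 probes and at tailbud for 468. Between sphere and 30% epiboly 232 probes passed from below the blank level at all earlier stages to above it at all later ones, and 234 passed the other way. At the step from 90% epiboly to tailbud these numbers were 350 and 10, at shield to 75% epiboly 310 and 2, and at 64-cell to high 19 and 155. These counts cannot be compared directly between steps. At the first and last steps 1 side is a single array, and the tailbud array had the most IDs above blanks (11274). From shield to 75% epiboly the median Cy5 signal rose by 1.59 on the log2 scale, its largest change.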

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

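The tests against the blank spots, in the pool channel, on array brightness, on the order of the later arrays and on the direction of the ratio were chosen only after the results were seen. Print-block loess was also added after the data were seen, though before its own value was known. Those on bright probes, on the order of the 9 stages and on a single step were set before their values were known, except that the spread of the single-step test over left-out arrays was added after its value was seen.

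Several control spots, left out of every comparison, gave a stage signal above the blank spots at all 9 stages. The 172 spots of CGENZFCTRL_40001_0 had a median Cy5 signal at least 14.9 times the 95th percentile of blanks, and their mean log2 ratio was -0.87 at 64-cell, -0.84 at sphere, -0.21 at 30% epiboly and 0.09 at tailbud. For the 31 spots named pooled control the lowest such multiple was 18.5, with log2 ratios of -1.08, -0.91, -0.15 and 0.04 at the same stages. For the 16 polyA spots it was 1.96, with log2 ratios of -0.13, 0.34, 0.58 and 0.81. For the first 2 kinds of spot most of the difference thus lay between sphere and 30% epiboly; which RNA they measure is not given in the sources used here.

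The pattern most worth following up is the break between sphere and 30% epiboly. Differences between arrays or hybridisations that also reach the pool channel are argued against by it, as 66 probes differed there at this step and up to 218 at others. The pool was always Cy3 and was quantile normalized between arrays. It therefore cannot show an effect confined to Cy5 or a shift of a whole array. A difference in array brightness is argued against by the step with the largest change of the median Cy5 signal, shield to 75% epiboly, which held 366 probes against 2250. Noise of dim probes is argued against by the 5369 brightest probes, of which 23.9% differed at this step and at most 4.02% at any other. What stays open, untested, is the stage itself, what the control spots' shift at this step stands for, and an array effect confined to Cy5. Also open is anything done once per stage RNA before hybridisation, such as amplification or a change in polyadenylation that alters what is amplified.

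The number of probes with a stage trend was weighed next. Of 100 orders of the 9 stages, the real one included, only the real one, 1 order, gave as many calls as 7198, which argues against a chance order at that level. The highest other order gave 6657 calls and had a rank correlation of 0.92 with the real order, while 98 orders gave 0. Shuffling the 9 stages cannot tell steady change from a single break after sphere, as few orders keep the early arrays together at 1 end. Nor can it tell stage from array differences that run with it. An absence of ordered change after 30% epiboly is argued against by the 6 later arrays alone, where 3356 of all tested probes were called. Only 1 of 100 orders, the real one, gave as many, and 94 gave 0. The highest other gave 3343, with a rank correlation of 0.94 with the real order. This test cannot tell stage from differences between arrays that run with it. The median Cy5 signal was 566, 453 and 324.5 from 30% epiboly to shield, and 980, 807 and 745 from 75% epiboly to tailbud. Within that limit, a step between sphere and 30% epiboly as the only change of every probe is argued against too. A single step per probe at differing boundaries is not, because later steps would also give calls on these arrays. Whether a step or a line describes most called probes stays open. A step between sphere and 30% epiboly left a smaller residual than the line for 48.3% of them, and for 45.9% to 51.1% when 1 array was left out. Among the line and a step at each of the 8 boundaries, the step after sphere had the smallest residual for 43.6% of them (3137) and the line for 32.8% (2363), a comparison that favours steps because there are 8 of them. Both comparisons cover only probes called by the linear fit, a selection that favours the line.

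A reading of red and green the wrong way round was tested on the pool, whose level should equal the mean of the 9 stages. As read here, the median log2 mean ratio of the 909 probes spanning at least 3 on the log2 scale differed from that of flat probes by -0.0938, and with the ratio inverted by 1.24, which argues against an exchange of the dyes.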

How the results depend on the processing

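Print-block loess, the omission of flagged spots or repeated IDs, the filter on blanks, the centred value table and the 6 later arrays were chosen after the data were seen. Aquantile scaling leaves ratios as they are and is not counted here. Of the recomputed counts 133 stayed within 1.5 times their value and 63 did not; of the values of named probes 143 kept direction and side of the threshold. The others were rarga's: its quadratic term lost its call without tailbud (1.40), and its uncalled fitted change turned positive with textbook hours (0.17), without 64-cell (0.51), high (0.28), shield (0.06) or 75% epiboly (0.11), and on the 6 later arrays, where it passed the threshold (1.80); leaving out 1 array gave -0.73 to 0.51. Except where stated, the cause was not tested. The break between sphere and 30% epiboly held 2188 probes after print-block loess, where no other step exceeded 352. Steps are given in stage order, by their first stage. Without background correction they held 81 (64-cell), 125 (30% epiboly), 25 (50% epiboly), 192 (shield), 81 (75% epiboly) and 106 (90% epiboly). With an offset of 10 they held 379 (30% epiboly), 167 (50% epiboly) and 563 (shield). Median centring gave 1009 positive quadratic terms and 85 probes for 50% epiboly, and 79 higher and 75 lower for 75% epiboly against 53 and 78. Textbook hours gave 554 negative and 225 positive ones. The value table as deposited gave 2103 rising, 2236 falling, 211 negative and 2851 positive terms; its steps, which hold the shift of each array's median, were 5753, 631, 787 (30% epiboly), 347, 2798, 765 and 865, and 7230 from 64-cell to tailbud. There the higher and lower probes were 348 and 283 for high, 213 and 134 for 50% epiboly, 2695 and 103 for shield, 152 and 613 for 75% epiboly, 164 and 701 for 90% epiboly, and 1660 and 5570 from 64-cell to tailbud. With medians subtracted it gave 581 against 462, and steps of 249, 626, 690 (30% epiboly; 437 higher, 253 lower), 307, 984, 700 (187 and 513) and 752 (227 and 525). Leaving out 1 array gave 75 to 1881 negative and 19 to 1146 positive terms, 2880 to 3916 rising and 2671 to 3529 falling probes; 73.9% of trend calls remained without 64-cell and 97.7% without 50% epiboly. The rank correlation gave 2182 falling. The 4-fold rule, stricter by construction, gave 18, 61, 455, 13, 6, 19, 9 and 7, and 1597 from 64-cell to tailbud. The filter on blanks gave 35 for 50% epiboly. Without flagged spots, with 13728 probes (CGENXEB_456014230_0 and CGENXEB_456011480_0 dropped out and gave no value), steps held 81 (64-cell), 12 (50% epiboly), 230 (shield) and 84 (75% epiboly). Print-block loess gave 149 for 30% epiboly. The 6 later arrays, fewer by construction, gave 1574 rising and 1782 falling. Not run were the gene list test, its estimated correlation and the mean over probes of a gene, as no probe list could be named, and a slide or scan-day block. Signal over blanks limits ratios of dim probes.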

Other observations

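All values in this part were looked at only after the data were seen, and no test was planned for them.

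In a dilution series of control spots, the difference between the log2 ratios of tailbud and 64-cell was 0.94 undiluted, 1.22 at a relative concentration of 0.5, 1.40 at 0.25 and 1.26 at 0.125. It was 0.68 at 0.0625, where the Cy5 signal at 64-cell was 0.801 times the 95th percentile of blanks, and -0.59, -0.20, -0.07 and -0.24 at 0.0312, 0.0156, 0.0078 and 0.0039. From 0.0312 down the Cy5 signal did not exceed that percentile at either stage, so these values and their signs are poorly measured. The spot at 0.0312 carries a slightly different series label. Each value is from 1 spot per array.

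Of the probe IDs, 116 lay on 2 spots and 11 on 3 or more. For the 116, the mean log2 intensities of both spots correlated at 0.80 across IDs, and their 9-stage profiles had a median correlation of 0.59. The profiles of 23 IDs correlated below 0. For the 59 IDs with a range of at least 1.5 the median was 0.93. For the 11 IDs on 3 or more spots, the mean log2 intensities of spots of an ID spanned 1.95 to 8.13. Spots of such an ID were averaged in the comparisons, as in the authors' value table, and leaving out all repeated IDs gave 3738 rising and 3396 falling probes.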
